A study of Mus musculus with 28 samples.

How the data were processed

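Liver RNA of 28 mouse samples was measured, 1 sample per array. Per the labels' protocols, 0.1 ug of RNA was amplified and marked with Cy3. Slides were read with Agilent Feature Extraction, version 10.7.3.1 per the file headers and 10.5 per the submitters' processing notes. The deposited scanner files hold, per the file headers, a processed intensity per spot on a linear scale, after subtraction of background and correction of trends within the array and with no scaling between arrays. They also hold the median intensity of each spot and of its background, and, as deposited, 0/1 flags for spots well above background, saturated or uneven. The deposited value table is on a log2 scale and quantile normalized between arrays, as its values show: array medians lie between 6.89 and 6.912. Its values follow the median spot intensity (correlation 0.9895 to 0.9994 per array) more closely than the processed one (0.917 to 0.9598). The authors' software for that step is not given in the sources used here.

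From the files, 1639 control spots were set aside and the log2 processed intensities of 43379 other spots were averaged over replicate spots to 41174 probes. Each array was scaled by subtracting the log2 of its 75th percentile. A probe was kept if it was well above background on all 4 arrays of at least 1 group, which held for 27509 probes and not for 13665. Gene symbols came from RefSeq accessions, matched without their versions: 28462 probes had a symbol and 12712 kept the accession of the file. The file headers name an older genome build than the table of symbols, so only names and the order of genes were used. Of 20303 features tested 14574 had a symbol. Where several probes passed, as for 5450 features, the probe with the highest mean signal over all arrays stood for the gene.

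Groups follow the genotype and dose in the labels, with 4 arrays in each of 7 groups. The limma package (version 3.58.1, with R 4.3.3 and the package data.table, 1.17.8) fitted a mean per group over the 28 arrays, with 21 residual degrees of freedom and moderated variances. It made 13 comparisons: each lowering of NTBC within each genotype, each genotype against another at the same dose, and the difference between genotypes in the response to reduced and to no NTBC. P-values were adjusted by the method of Benjamini and Hochberg over all features of a comparison, and genes with an adjusted p under 0.05 were called. For counts adjusted over the list alone the same p-values were adjusted over the members of that list. Genes called in a pair of comparisons in the same direction were counted beside the number expected of independent calls. Where the pair shared a group, 20 simulations of unchanged groups against the shared arrays, and splits of these arrays, were run as well.

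The 35 gene lists, among them markers of cell types, and their members were written before the data were examined, as were the comparisons, the tests, the rule for genes named and most alternatives. Each list was tested in each comparison with camera, with a preset correlation between genes of 0.01, and adjusted over all 455 tests. Median log2 fold changes of a list are over its measured members. List levels per array are means of the members' log2 levels relative to the 75th percentile.

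The genes named were drawn from those that the rule allows. In every comparison it allows the targeted genes Fah, Trp53 and Cdkn1a. It also allows up to 10 of the largest rises and 10 of the largest falls among called genes with separate arrays, up to 4 called members of each list, and a fixed panel of p53, oxidant, cell cycle and liver genes. Of these the text names fewer, chosen after the values were seen, and mostly genes whose call held under the alternatives. Some genes the rule allows are withheld and not reported here.

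The alternatives were normexp background correction with an offset of 50, quantile normalization, the deposited value table, no filter, a filter on all 28 arrays, the mean of a gene's probes, a fit to the groups compared alone, variances with a trend and robust to outlying genes, the replicate number as a block, slide as a random or fixed block, comparisons within a slide, a minimum change of 2-fold, each array left out in turn, an estimated correlation between genes, and the fry test. The normexp alternative had been planned on mean spot intensities, which are not among the columns of these files, and used the median intensities of spot and background. After the data were seen, a term for sex (in 1 test together with slide), male or female arrays alone, the leaving out of the arrays farthest from their groups, and slide as a fixed block with the spread of all 28 arrays were added.

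The procedures were tested on simulated independent genes. For reduced against full NTBC in Fah-/- mice, 74% of 100 genes changed by a log2 of 1 were called. So were 96% of 100 changed by 2 and 12 of 20065 unchanged. In Fah-/- p53-/- mice with nothing changed, 0 of 20303 were. For the difference between genotypes in the response to no NTBC, 89% of 100 genes changed by 2 were called. A shifted list was called in 4 of 4 comparisons and no unshifted test checked was, with correlated genes untested.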

Results

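The data were 28 single-colour Agilent whole mouse genome arrays of liver RNA, 4 arrays in each of 7 groups. All mice lacked fumarylacetoacetate hydrolase (Fah), the final enzyme of tyrosine breakdown, whose loss in people causes hereditary tyrosinemia type I. Such mice are kept alive by nitisinone (NTBC), a drug that blocks the upstream enzyme Hpd and so keeps toxic tyrosine metabolites from forming. Fah-/- mice and Fah-/- mice that also lacked p53 were sampled at full dose, at a reduced dose and with no NTBC, and Fah-/- mice that also lacked the cell cycle inhibitor p21 were sampled with no NTBC. The full dose was 7.5 mg/L in the drinking water. For the reduced dose the labels conflict: those of the samples give 25% of the full dose, the series' own design and treatment notes 2.5% for 3 months, so it is called the reduced dose here. How long the mice with no NTBC had gone without the drug is not given in the sources used here.

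The 75th percentile of the processed signal ranged from 252 to 578 over the 28 arrays, and 54.8% to 68.5% of the probes lay well above background. All 28 passed the scanner software's own quality range. The labels do not say that the 4 samples of a group came from separate animals, so the p-values measure only the spread between these samples. The arrays were scanned in 3 runs that coincide with the 3 doses, so dose and run cannot be told apart, while genotypes were compared within a run. At full and reduced dose each genotype filled a slide of its own, so there genotype and slide cannot be told apart either. The 12 arrays with no NTBC were spread over 3 slides with 2 groups on each.

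Sex differed between groups. On all 4 arrays of 5 groups the Y-linked transcript Ddx3y was well above background, and Xist, made from the inactive X, was not. The 4 Fah-/- p53-/- arrays with no NTBC showed the reverse, so their RNA came from females. Of the 4 Fah-/- p21-/- arrays, replicates 1 and 2 were female and 3 and 4, on another slide, male. A term for sex alone rests on these 4 arrays and carries slide with it. The arrays farthest from the other replicates of their group were Fah-/- p53-/- replicate 1 with no NTBC (standard deviation over genes 0.793), Fah-/- p21-/- replicate 1 (0.661) and Fah-/- p21-/- replicate 2 (0.554).

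Changes are given as log2 fold changes ± SE from 1 limma fit over the 28 arrays, with n = 4 arrays per group and p-values adjusted over 20303 genes. A gene was called, and is said to have risen or fallen, at an adjusted p under 0.05. Of the genes named with a call, all 4 arrays of one group lay on the same side of all 4 of the other unless said otherwise. Where the lower group was not above background, a fold is given as at least that over the background level. These bounds depend on the scaling: the folds with normexp and with the deposited values, given behind them in that order, were smaller for all 24. Lists of genes were tested with camera and a preset correlation between genes, and 203 of 455 such tests had an adjusted p under 0.05. With a correlation estimated from the arrays 3 did, namely the male-biased and female-biased liver transcripts for p53 loss at full NTBC and the p53 targets for p53 loss against p21 loss. That adjusted p is given with each list as estimated-correlation p, and is the highest over the alternatives tried unless another p is given beside it.

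**Figure D1:**
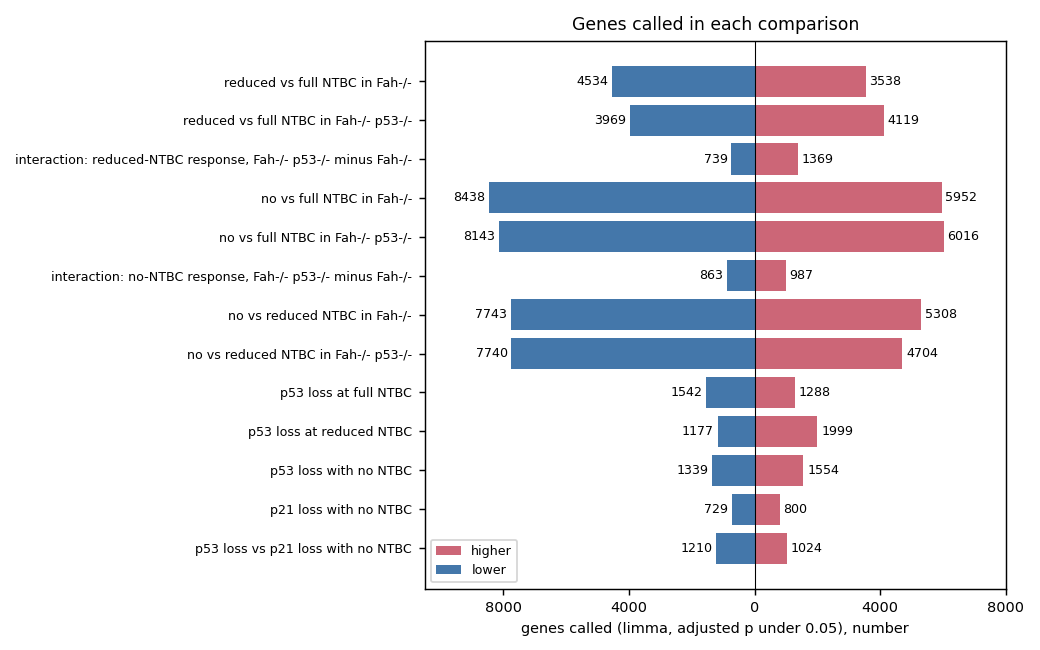
Number of genes called at an adjusted p under 0.05 (limma, 4 arrays per group) in each of the 13 comparisons, with genes higher in the first-named group to the right and lower ones to the left, and for interactions the sign of the difference between responses. The comparison of no with full NTBC in Fah-/- mice called the most, 5952 higher and 8438 lower, and that of p21 loss the fewest, 800 higher and 729 lower.

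The targeted genes showed signal on every array. Cdkn1a, which encodes p21, was at a log2 level of -1.40 ± 0.41 (SD, n = 4, relative to the array's 75th percentile) in Fah-/- mice on full NTBC, 1.48 ± 0.64 on reduced NTBC and 4.28 ± 0.10 with none. In Fah-/- p53-/- mice the levels were -2.93 ± 0.38, 0.05 ± 1.38 and 3.30 ± 0.32. Cdkn1a was lower in Fah-/- p53-/- than in Fah-/- mice by -1.53 ± 0.43 on full NTBC (adjusted p = 0.018) and by -1.43 ± 0.43 on reduced NTBC (0.0238, arrays of the groups overlapping), and with no NTBC the difference of -0.98 ± 0.43 did not pass (0.126). The call on full NTBC was lost with normexp background correction (0.654, the highest of its alternatives), with the deposited values (0.148) and without Fah-/- replicate 1 (0.0517) or 2 (0.0584) or Fah-/- p53-/- replicate 4 (0.056). The call on reduced NTBC was lost with normexp (0.24, likewise the highest), with a fit to the groups compared alone (0.153) and without Fah-/- replicate 1 (0.0923) or Fah-/- p53-/- replicates 1 (0.0988) or 4 (0.0992). On the arrays labelled p21-/- the Cdkn1a probe read 3.24 ± 0.22, which differed from Fah-/- by -1.05 ± 0.43 (adjusted p = 0.139), so this probe does not check that label.

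Trp53, which encodes p53, had a pair of probes that disagreed. The dimmer probe was lower in Fah-/- p53-/- than in Fah-/- mice by -1.38 ± 0.17 on full NTBC (adjusted p over probes 3.59e-06), by -1.96 ± 0.17 on reduced NTBC (9.73e-08) and by -2.15 ± 0.17 with none (2.54e-08). The brighter probe, used for the gene, differed by -0.20 ± 0.14, 0.26 ± 0.14 and -0.27 ± 0.14, none of which passed. Where the probes lie relative to the deleted parts of Trp53 and Cdkn1a was not analysed here. The Fah probe fell from -0.20 ± 0.14 on full NTBC to -2.11 ± 0.41 with none in Fah-/- mice (change -1.91 ± 0.21, adjusted p = 2.4e-08), and was at -0.07 ± 0.06 on reduced NTBC (change 0.14 ± 0.21, not called).

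**Figure D2:**
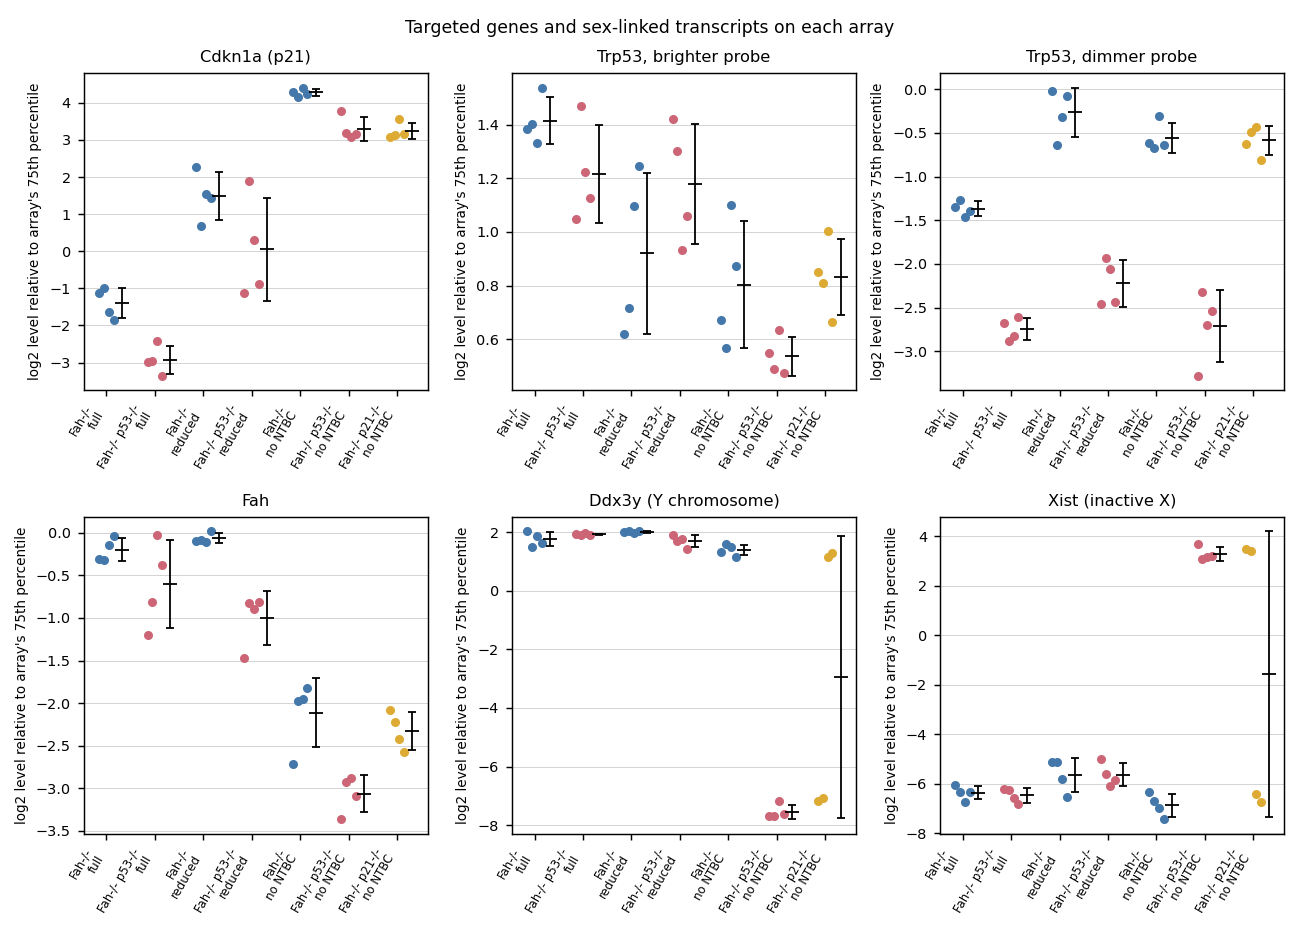
Log2 level relative to the array's 75th percentile of Cdkn1a, both Trp53 probes, Fah, Ddx3y and Xist in the 7 groups, with 1 point per array and the mean ± SD of the 4 arrays beside them in black. The dimmer Trp53 probe was lower on every p53-/- array than on any other.

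On reduced against full NTBC, genes of the oxidant response and of p53 were higher in livers of Fah-/- mice. The largest rise was that of the carbonyl reductase Cbr3 at 6.74 ± 0.32 (adjusted p = 8.55e-13). The cystine importer Slc7a11 rose at least 20-fold (4.84 and 5.76; 2.64e-09), the glutathione-cleaving Ggt1 at least 9.25-fold (2.41 and 2.93; 1.42e-09) and the efflux transporter Abcc4 by 4.66 ± 0.28 (3.13e-11). Of 38 measured NRF2 targets, the genes of the antioxidant transcription factor, 23 rose and 3 fell (25 and 3 adjusted over the list alone; median 0.90, list adjusted p = 9.96e-10, estimated-correlation p = 0.384). They included Nqo1, a quinone reductase (2.09 ± 0.20), the glutathione transferase Gsta2 (2.34 ± 0.35), the glutathione-making Gclc (1.63 ± 0.17), and the heme-degrading Hmox1 (1.32 ± 0.28, the largest adjusted p of these at 0.000695). Of 34 p53 targets 17 rose and 5 fell (18 and 5 over the list; median 0.53, 0.000456, estimated-correlation p = 0.331). Cdkn1a rose by 2.89 ± 0.43 (1.29e-05), the death receptor Eda2r at least 9.29-fold (2.49 and 2.99; 1.23e-07), the AKT inhibitor Phlda3 by 2.82 ± 0.27 (5.35e-08), Ccng1 by 1.76 ± 0.20 (5.57e-07), the p53 ubiquitin ligase Mdm2 by 0.62 ± 0.12 and the pro-apoptotic Bax by 0.67 ± 0.13 (0.000297 and 0.000316). Among 29 fetal liver and liver tumour markers 9 rose and 1 fell (the same counts over the list; median 0.61, 0.00316, estimated-correlation p = 0.595). Gpc3, a glypican of fetal liver, changed by 3.45 ± 0.43. The metal-binding metallothioneins Mt1 and Mt2 rose by 2.90 ± 0.33 and 3.88 ± 0.29, and the surface protein gene Ly6d by 4.35 ± 0.40.

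Genes of the mature hepatocyte were lower in the same comparison. Of 35 secreted plasma proteins 28 fell and 0 rose (30 and 0 over the list; median -0.78, list adjusted p = 1.97e-11, estimated-correlation p = 0.25), among them the complement component C8b (-2.49 ± 0.43) and the fibrinogen chain Fga (-1.57 ± 0.19). Of 29 genes of the urea cycle and amino acid breakdown 14 fell and 0 rose, over all genes and over the list (median -0.51, 0.00115, estimated-correlation p = 0.7). Histidine ammonia-lyase Hal changed by -1.87 ± 0.36, Cbs at -1.47 ± 0.24 and the urea cycle enzyme Ass1 at -1.31 ± 0.30. In tyrosine breakdown 4 of 6 members fell, also over the list (median -0.79, list adjusted p = 0.0384). Tat and Hpd, the first steps of the pathway, fell by 1.74 ± 0.26 and 1.17 ± 0.22. The call on this list was lost with an estimated correlation (adjusted p = 0.653, the highest of its alternatives), with quantile normalization (0.088), with the deposited values, with probes above background on all 28 arrays, and without Fah-/- replicate 4 on full NTBC (0.0525). Of 24 cholesterol synthesis genes 12 fell and 0 rose (15 and 0 over the list; median -0.71, list adjusted p = 0.000689, estimated-correlation p = 0.724). Fdps changed by -1.48 ± 0.33 and Nsdhl at -1.32 ± 0.28. Of 20 transcripts that male livers make more of than female livers, 11 fell and 1 rose, also over the list (median -0.91, list adjusted p = 0.000236, estimated-correlation p = 0.537), led by the steroid dehydrogenase Hsd3b5 at -7.98 ± 0.78 and the fatty acid elongase Elovl3 at -4.55 ± 0.89. In all 8072 of 20303 genes were called, 3538 higher and 4534 lower. With normexp background correction 1996 genes were called.

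In Fah-/- p53-/- mice many of the same antioxidant genes, together with some fetal genes, were higher on reduced than on full NTBC. Cbr3 rose by 7.05 ± 0.32 (adjusted p = 8.63e-13), the glutathione transferase Mgst2 by 6.23 ± 0.32 (4.63e-12), Ggt1 by 5.41 ± 0.38, Abcc4 by 4.59 ± 0.28, Gclc by 1.77 ± 0.17 and Nqo1 by 1.37 ± 0.20 (1.28e-05, the largest adjusted p of these). Of 38 NRF2 targets 26 rose and 1 fell (27 and 3 over the list; median 0.94, list adjusted p = 8.72e-10, estimated-correlation p = 0.384). The imprinted fetal growth factor Igf2 rose by 5.75 ± 0.80 (7.58e-06), its neighbour H19 by 6.25 ± 0.68 (3.05e-07), Gpc3 by 5.31 ± 0.43 and the growth regulator Myc by 2.20 ± 0.32. Of 29 fetal markers 8 rose and 3 fell (10 and 3 over the list; median 0.55, list adjusted p = 0.0128, estimated-correlation p = 0.653), with a median of -0.09 with normexp. Among 34 p53 targets 13 rose and 7 fell (14 and 7 over the list). Cdkn1a changed by 2.98 ± 0.43 (9.7e-06), Ccng1 at 0.66 ± 0.20 (0.0116) and Mdm2 at 0.64 ± 0.12 (0.000203), while the list as a whole did not pass (median 0.30, list adjusted p = 0.128). Of 34 genes of G2/M and mitosis 10 rose and 0 fell, also over the list (median 0.97, 0.0029, estimated-correlation p = 0.828). With normexp this list's median was -0.03, against -0.35 for all genes, and its call was lost.

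Lipid synthesis, plasma proteins and clock genes were lower in Fah-/- p53-/- mice on reduced NTBC. Of 24 cholesterol synthesis genes 22 fell and 0 rose (24 and 0 over the list; median -1.42, list adjusted p = 1.71e-12, estimated-correlation p = 0.453), among them Mvd (-2.90 ± 0.32) and Fdps (-1.94 ± 0.33). Of 24 lipogenesis genes 14 fell and 2 rose, also over the list (median -0.84, 0.0029, estimated-correlation p = 0.573, and adjusted p = 0.879 with normexp). Fatty acid synthase Fasn changed by -2.16 ± 0.30, the desaturase Scd1 at -2.94 ± 0.49 and Thrsp at -4.32 ± 0.90. Of 35 plasma proteins 29 fell and 0 rose (30 and 0 over the list; median -0.73, 2.16e-12, estimated-correlation p = 0.248, and adjusted p = 0.887 with normexp), including C8b (-2.33 ± 0.43) and the clotting factors F12 (-1.61 ± 0.15) and F7 (-1.49 ± 0.17). The acute phase proteins Saa1 and Saa2 fell by 3.27 ± 0.53 and 4.25 ± 0.65, the urinary protein Mup3 by 3.73 ± 0.92, Mt1 by 1.86 ± 0.33 and Tat by 1.44 ± 0.26 (0.00246, for Mup3, the largest adjusted p of these). Of 19 circadian clock genes 11 fell and 2 rose, also over the list (median -0.85, 0.0174, estimated-correlation p = 0.653). The call was lost with normexp and with probes above background on all 28 arrays. Dbp fell by 3.32 ± 0.59 and Per3 by 2.71 ± 0.46, while Arntl, which peaks at the opposite time, rose by 2.64 ± 0.44. Of 24 endothelial markers 13 fell and 0 rose, also over the list (median -0.46, 0.000226, estimated-correlation p = 0.568, and adjusted p = 0.712 with normexp). In all 8088 genes were called, 4119 higher and 3969 lower, or 50.9% higher. With normexp 24.5% of the called genes were higher, with a median over all genes of -0.35 against 0.03.

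The response to reduced NTBC differed between the genotypes for 2108 genes, 1369 with a more positive and 739 with a more negative response in Fah-/- p53-/- mice. The metallothioneins moved in opposite directions: Mt2 changed by 3.88 in Fah-/- and by -1.56 in Fah-/- p53-/- mice (difference -5.44 ± 0.41, adjusted p = 1.61e-08) and Mt1 by 2.90 and -1.86 (-4.76 ± 0.46, 1.02e-06). Igf2 changed by 5.75 in Fah-/- p53-/- against -0.47 in Fah-/- mice (6.22 ± 1.14, 0.00133) and H19 by 6.25 against 0.61 (5.64 ± 0.96, 0.000707). The male-biased genes Hsd3b5 and Hsd3b4 fell in Fah-/- mice by 7.98 and 7.46, and changed by -0.59 and -0.22 in Fah-/- p53-/- mice (differences 7.39 ± 1.10 and 7.24 ± 0.83, largest adjusted p = 0.000209). The organic anion transporter genes Slc22a26 and Slco1a4 responded more negatively in Fah-/- p53-/- mice (-5.00 ± 0.59, or -3.14 with normexp, and -4.16 ± 0.62), and the stress gene Gadd45g more positively (3.88 ± 0.63). Of 34 p53 targets 7 were more negative and 0 more positive in Fah-/- p53-/- mice, also over the list. They included Phlda3 (-2.38 ± 0.38, adjusted p = 0.000384) and Ccng1 (-1.10 ± 0.29, 0.0166, not called with normexp). Cdkn1a (0.10 ± 0.60, 0.945) and Mdm2 (0.02 ± 0.17, 0.952) did not pass. The list's median was -0.06 (list adjusted p = 0.0145, estimated-correlation p = 0.532), and its call was lost with normexp, with no filter on dim probes and without Fah-/- replicate 1 on reduced NTBC (0.0806). Without Fah-/- replicate 2 on reduced NTBC 1398 genes were called, and with normexp 78, 75.6% of them more positive, against 64.9%.

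With no against full NTBC, livers of Fah-/- mice had lower hepatocyte genes and higher fetal, p53 and oxidant response genes. Slc7a11 rose at least 377-fold (78.7 and 98.7; adjusted p = 3.26e-14), Igf2 by 9.82 ± 0.80 (2.18e-10), Ggt1 at least 125-fold (26.4 and 30.9; 1.48e-14), H19 by 7.68 ± 0.68, Ly6d by 7.38 ± 0.40 and Afp, the fetal serum albumin, by 7.09 ± 0.57 (1.49e-10). Of 29 fetal liver and liver tumour markers 28 rose and 0 fell, also over the list (median 2.86, list adjusted p = 4.39e-10, estimated-correlation p = 0.199). Among 34 p53 targets 23 rose and 3 fell (23 and 4 over the list; median 0.93, 1.07e-05, estimated-correlation p = 0.199). Cdkn1a rose by 5.68 ± 0.43 or 51.4-fold (5.16e-11), Phlda3 by 5.04 ± 0.27, Eda2r at least 23.8-fold (4.87 and 5.78), Ccng1 by 2.62 ± 0.20, Mdm2 by 2.08 ± 0.12 and Bax by 1.34 ± 0.13 (4.69e-09, the largest adjusted p of these). Of 38 NRF2 targets 25 rose and 8 fell, also over the list (median 0.69, 0.000416, estimated-correlation p = 0.653). Hmox1 changed by 3.42 ± 0.28, the peroxiredoxin reductase Srxn1 at 3.47 ± 0.30 and Nqo1 at 2.43 ± 0.20. Of 34 G2/M and mitosis genes 22 rose and 1 fell, also over the list (median 1.52, 0.000903, estimated-correlation p = 0.786). Their median was 0.20 with normexp.

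Markers of other liver cells rose beside these. Of 32 macrophage and monocyte markers 26 rose and 0 fell, also over the list (median 1.24, list adjusted p = 2.37e-05, estimated-correlation p = 0.675), among them the galectin Lgals3 (4.29 ± 0.38) and the lysosomal membrane protein Cd63 (4.60 ± 0.27). Of 22 bile duct and progenitor cell markers 15 rose and 3 fell, also over the list (median 1.54, 0.00201, estimated-correlation p = 0.568). The tight junction protein Cldn4 was at least 16.8-fold higher (4.10 and 4.99). Plaur, the urokinase receptor, rose by 5.86 ± 0.32.

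Hepatocyte genes fell in step. All 35 plasma protein genes measured fell, also over the list (median -2.15, list adjusted p = 7.22e-13, estimated-correlation p = 0.229), including C8b (-6.74 ± 0.43) and F7 (-4.67 ± 0.17). Of 29 urea cycle and amino acid genes 28 fell and 0 rose, also over the list (median -2.09, 3.24e-08, estimated-correlation p = 0.515). Hal changed by -4.89 ± 0.36. All 6 tyrosine breakdown genes fell, also over the list (median -1.87, 0.00396, estimated-correlation p = 0.532). Tat changed by -2.92 ± 0.26 and Hpd at -2.89 ± 0.22. Of 28 hepatocyte cytochrome P450 genes 20 fell and 2 rose, also over the list (median -1.62, 0.000607, estimated-correlation p = 0.653). Cyp2c54 changed by -7.66 ± 0.56 and Cyp2e1 at -3.17 ± 0.38. Of 24 cholesterol synthesis genes 20 fell and 0 rose, also over the list (median -1.85, 3.66e-05, estimated-correlation p = 0.667). The sterol reductase Tm7sf2 changed by -4.81 ± 0.24. Hsd3b5 fell by 11.14 ± 0.78, Elovl3 by 9.46 ± 0.89, Scd1 by 5.53 ± 0.49 and G6pc, the phosphatase that releases glucose, by 3.78 ± 0.36. In all 14390 genes were called, 5952 higher and 8438 lower (41.4% higher). The median of all genes was -0.17, against 0.01 with quantile normalization and -0.40 with normexp, with which 31.0% of the calls were higher. List medians moved by more than these shifts: with quantile normalization they were -1.12 for plasma proteins, -0.725 for cytochrome P450 and 1.42 for NRF2 targets.

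In Fah-/- p53-/- mice the differences between no and full NTBC had largely the same shape. Slc7a11 rose at least 169-fold (15.6 and 37.4; adjusted p = 1.38e-13), the keratin Krt20 by 8.92 ± 0.64 (2.35e-11), Mgst2 by 7.81 ± 0.32 (4.43e-15), Cbr3 by 7.43 ± 0.32, Afp by 6.65 ± 0.57 and Gpc3 by 6.27 ± 0.43. Of 29 fetal markers 25 rose and 1 fell, also over the list (median 2.36, list adjusted p = 1.05e-07, estimated-correlation p = 0.25). Of 34 p53 targets 23 rose and 7 fell, also over the list (median 0.81, 0.000801, estimated-correlation p = 0.345; median 0.33 with normexp). Cdkn1a changed by 6.23 ± 0.43 (9.88e-12), Mdm2 at 1.46 ± 0.12, Ccng1 at 1.51 ± 0.20 and the stress factor Gdf15 at 1.36 ± 0.31 (0.000444, the largest adjusted p of these). Of 38 NRF2 targets 25 rose and 6 fell, also over the list (median 0.79, 0.00031, estimated-correlation p = 0.653). Hmox1 changed by 2.59 ± 0.28. Of 34 G2/M and mitosis genes 27 rose and 1 fell (29 and 1 over the list; median 1.97, 7.44e-05, estimated-correlation p = 0.739; median 0.50 with normexp). Of 32 macrophage markers 21 rose and 0 fell (19 and 0 over the list; median 1.18, 0.000217, estimated-correlation p = 0.724). Lgals3 changed by 4.53 ± 0.38 and Cd63 at 4.19 ± 0.27. Of 22 bile duct and progenitor markers 14 rose and 2 fell, also over the list (median 1.66, 0.000884, estimated-correlation p = 0.532). Cldn4 was at least 15.1-fold higher (2.16 and 4.50).

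The falls in Fah-/- p53-/- mice covered 34 of 35 plasma proteins (median -2.38, list adjusted p = 8.06e-14, estimated-correlation p = 0.199), 28 of 29 urea cycle and amino acid genes (-2.53, 3.29e-10, estimated-correlation p = 0.453) and all 6 tyrosine breakdown genes (-2.50, 0.0016, estimated-correlation p = 0.471). They also covered 25 of 28 cytochrome P450 genes (-2.09, 3.06e-06, estimated-correlation p = 0.532) and all 24 cholesterol synthesis genes (-2.73, 4.35e-08, estimated-correlation p = 0.568). None of these 5 lists had a member that rose, and the counts over the list were equal. The iron hormone gene Hamp2 fell by 8.67 ± 0.60, Saa2 by 8.47 ± 0.65, the carboxylesterase Ces3b by 8.47 ± 0.47, the male-biased Mup3 fell by 7.84 ± 0.92 (by 3.85 with a term for sex), Hal by 6.15 ± 0.36, Tm7sf2 by 5.35 ± 0.24, F7 by 4.90 ± 0.17, Hpd by 3.18 ± 0.22 and Tat by 3.00 ± 0.26. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 4.49 ± 0.54 (adjusted p = 1.17e-07). In all 14159 genes were called, 6016 higher and 8143 lower (42.5% higher). The median of all genes was -0.14, against 0.02 with quantile normalization and -0.41 with normexp, with which 32.2% of the calls were higher. The arrays compared here differ in sex, female with no NTBC and male on full NTBC.

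**Figure D3:**
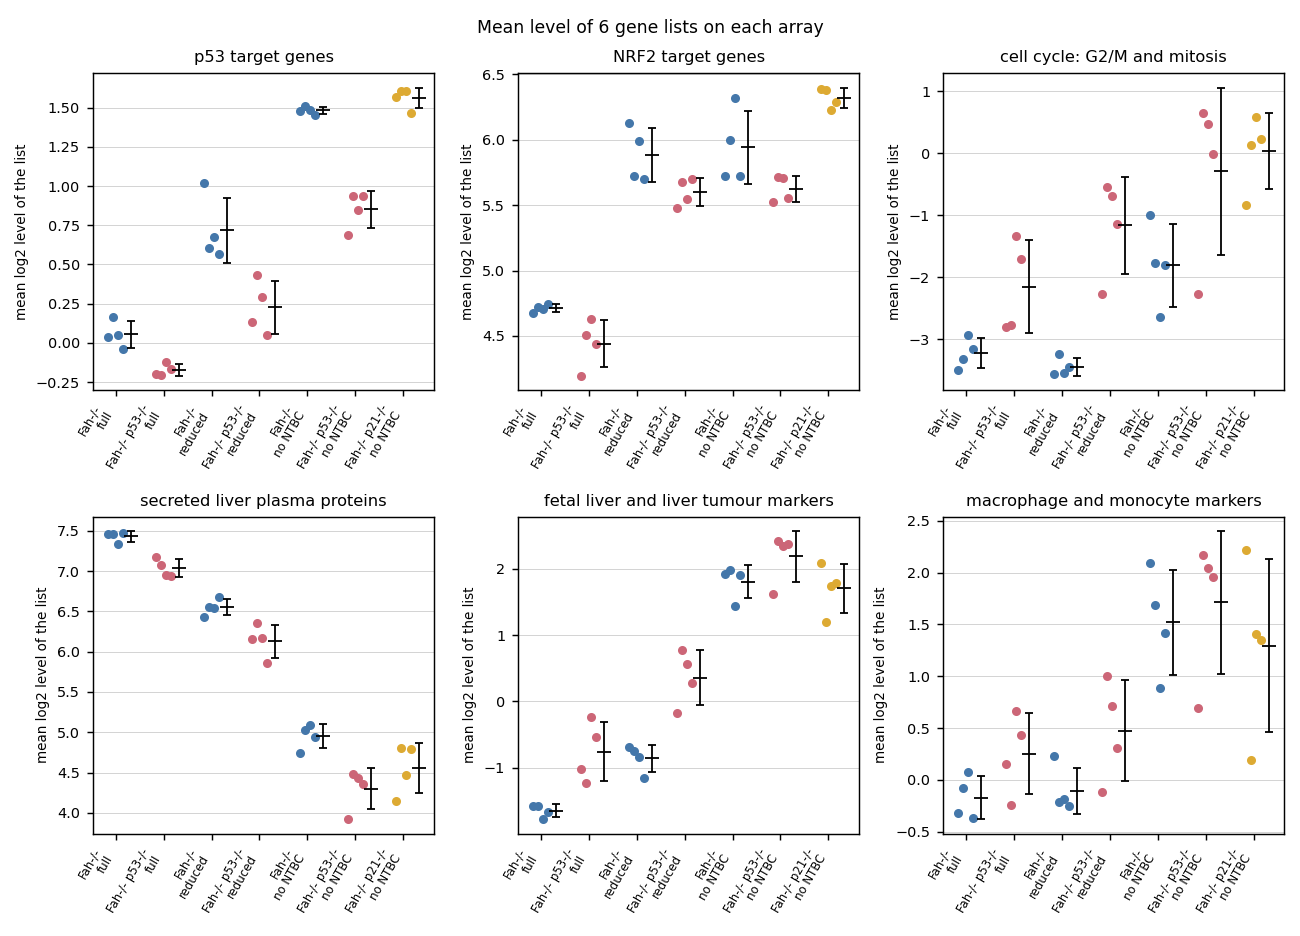
Mean log2 level of the members of 6 gene lists on each array, relative to the array's 75th percentile, with 1 point per array in 7 groups and the mean ± SD of 4 arrays beside them in black. From full to reduced to no NTBC the plasma proteins step down and the fetal markers step up in group means of both genotypes, except that with normexp the plasma proteins' call on reduced NTBC in Fah-/- p53-/- mice is lost; for mitosis genes and fetal markers on reduced NTBC in Fah-/- p53-/- mice normexp turns the medians to -0.03 and -0.09.

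The response to no NTBC differed between genotypes for 1850 genes, 987 more positive and 863 more negative in Fah-/- p53-/- mice. The Fah-/- p53-/- arrays with no NTBC were female and the others here male. Xist differed by 10.26 ± 2.11 (adjusted p = 0.00326) and Ddx3y by -9.11 ± 1.73 (0.00183), which a term for sex brought to 0.24 ± 0.56 and -0.77 ± 0.25, with neither called. The call of Xist was lost also with normexp. The largest differences of other genes included sex-biased ones, called with the term as well: Hsd3b5 fell by 11.14 in Fah-/- mice and changed by 0.21 in Fah-/- p53-/- mice, where it was already low on full NTBC (difference 11.35 ± 1.10, adjusted p = 5.38e-07; 12.53 with the term). Elovl3 (8.05 ± 1.26, 0.000274) and Cyp4a12a (5.37 ± 0.88, 0.000441) differed likewise, and the female-biased Sult2a6 (-6.82 ± 0.98, 1e-04) and Slc22a26 (-6.16 ± 0.59, 4.04e-07) in the opposite direction. Each already differed on full NTBC. Of 34 p53 targets 7 were more negative and 1 more positive in Fah-/- p53-/- mice (11 and 2 over the list, median -0.45, list adjusted p = 0.0011, estimated-correlation p = 0.381). Phlda3 differed by -2.21 ± 0.38 (0.000672), the apoptosis activator Bbc3 by -1.73 ± 0.24 (7.03e-05), Ccng1 by -1.11 ± 0.29 (0.0157) and Mdm2 by -0.62 ± 0.17 (0.0234), and Cdkn1a by 0.55 ± 0.60 (0.626, not called). The Mdm2 call was lost without Fah-/- replicate 2 (0.0534) or Fah-/- p53-/- replicate 3 (0.0518) with no NTBC. A term for sex also ended it (-0.66 ± 0.25, 0.155, the highest of its alternatives) and that of Ccng1 (-1.06 ± 0.41), both with a larger SE. Of 24 cholesterol synthesis genes 4 responded more negatively and 0 more positively (11 and 0 over the list; median -0.77, 4.77e-06, estimated-correlation p = 0.64), and Cyp7a1 did so by -4.07 ± 0.77 (0.00172). The inflammasome-family gene Nlrp12 fell by more in Fah-/- mice (7.39 ± 0.92, 1.86e-05). Sizes depend on the scaling where a group was at background: with normexp and with the deposited values Nlrp12 differed by 3.67 and 3.31, Xist by 5.12 and 5.56, Ddx3y by -3.73 and -4.05, Hsd3b5 by 7.55 and 7.63 and Slc22a26 by -3.17 and -4.34. With normexp 241 genes were called and with a term for sex 605.

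From reduced to no NTBC fetal, bile duct and macrophage genes rose and plasma proteins fell in both genotypes. In Fah-/- mice Igf2 rose by 10.29 ± 0.80 (adjusted p = 3.87e-10), Krt20 at least 82.4-fold (19.6 and 17.9), H19 by 7.06 ± 0.68, Afp by 6.28 ± 0.57, Cdkn1a by 2.80 ± 0.43, Hmox1 by 2.10 ± 0.28 and Mdm2 by 1.46 ± 0.12, while Hamp2 fell by 6.39 ± 0.60, Cyp2c54 by 6.33 ± 0.56, Fah by 2.05 ± 0.21 and Hpd by 1.72 ± 0.22 (largest adjusted p of these 5.61e-06). In Fah-/- p53-/- mice Krt20 rose by 7.34 ± 0.64, the cytochrome Cyp2s1 by 6.42 ± 0.42, Afp by 5.24 ± 0.57, Cdkn1a by 3.25 ± 0.43, Hmox1 by 1.73 ± 0.28 and Mdm2 by 0.82 ± 0.12, while Hamp2 fell by 7.40 ± 0.60, Cyp7a1 by 2.99 ± 0.54, Hpd by 2.06 ± 0.22 and Fah by 2.06 ± 0.21 (largest 5.4e-05). Of 29 fetal markers 27 rose and 0 fell in Fah-/- mice (median 1.82, list adjusted p = 1.61e-09, estimated-correlation p = 0.199) and 20 rose and 1 fell in Fah-/- p53-/- mice (21 and 1 over the list; 1.66, 2.37e-07, estimated-correlation p = 0.28). Of 22 bile duct and progenitor markers 17 rose and 2 fell in the former (2.05, 4.3e-06, estimated-correlation p = 0.331) and 14 rose and 2 fell in the latter (15 and 2 over the list; 1.78, 4.36e-06, estimated-correlation p = 0.331). Of 33 stellate cell and matrix genes 23 rose in Fah-/- mice (1.07, 6.14e-05, estimated-correlation p = 0.692) and 19 in Fah-/- p53-/- mice (0.74, 0.000289, estimated-correlation p = 0.724), and 0 fell in either. Of 32 macrophage markers 27 and 19 rose and 0 fell (1.26 and 0.99, 2.46e-06 and 1.77e-05, and adjusted p = 0.653 and 0.669 with an estimated correlation). Of 35 plasma proteins 31 fell and 1 rose in Fah-/- mice (32 and 1 over the list; -1.43, 8.72e-10, estimated-correlation p = 0.32) and 32 fell and 0 rose in Fah-/- p53-/- mice (-1.67, 8.4e-12, estimated-correlation p = 0.25). Counts over the list equal the others where none are given. Of 38 NRF2 targets 8 rose and 11 fell in Fah-/- mice and 8 rose and 16 fell in Fah-/- p53-/- mice, and the list passed in neither (medians -0.18 and -0.29, adjusted p = 0.983 for both, with median, mean and test differing in sign). In all 13051 genes were called in Fah-/- mice, 5308 higher and 7743 lower, and 12444 in Fah-/- p53-/- mice, 4704 higher and 7740 lower. With normexp 6755 and 5698 were called. In Fah-/- p53-/- mice 48.6% of the calls were higher with the deposited values, against 37.8%, and the medians of all genes were -0.14 and -0.16 here.

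The responses overlapped beyond independent calls, but the genotypes share runs, whose effects could overlap too. In Fah-/- mice 5838 genes moved the same way on reduced and no NTBC, 2228 higher and 3610 lower, against 1037 and 1884 for independent calls. Another 608 went the opposite way. Both comparisons share the full-dose arrays, which alone gave a correlation across genes of 0.497 in simulated unchanged groups, against 0.605 observed. With the full-dose arrays split between the comparisons the correlation was 0.545 to 0.576 and 3874 to 4401 genes moved the same way. With quantile normalization 48.3% of the shared genes were higher, against 38.2%, and with normexp 1529 genes were shared. Between the genotypes 4273 genes moved the same way on reduced NTBC, 1952 higher and 2321 lower, against 717.8 and 886.3 for independent calls. Another 192 went the opposite way (correlation across genes 0.593). With normexp 1080 were shared. With no NTBC 11674 genes moved the same way in both genotypes (4726 higher and 6948 lower, against 1764 and 3384) and 182 in opposite directions, with a correlation of 0.869. Of these 40.5% were higher, against 29.7% with normexp and 51.0% with the deposited values. Genes are not independent replicates, so these correlations carry no p-value.

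On full NTBC the loss of p53 went with a switch of sex-biased liver genes, although all 8 arrays were male by Ddx3y and Xist. The female-biased sulfotransferase genes Sult2a6 (10.91 ± 0.70, adjusted p = 1.05e-10), Sult2a3 (at least 234-fold; 34.2 and 51.6; 1.97e-09) and Sult2a4 (at least 177-fold; 24.3 and 38.0; 2.39e-11) were higher in Fah-/- p53-/- than in Fah-/- mice, as were the oxidase Hao2 (7.10 ± 0.71), the transporter Slc22a26 (6.77 ± 0.41) and Cux2, a transcription factor of female liver (at least 17.4-fold; 4.30 and 4.65). Of 24 female-biased transcripts 19 were higher and 1 lower, also over the list (median 2.94, list adjusted p = 1.66e-18, estimated-correlation p = 0.0224). The male-biased genes Hsd3b5 (-10.80 ± 0.78), Hsd3b4 (-8.67 ± 0.59), Elovl3 (-7.79 ± 0.89), Cyp4a12a (-7.24 ± 0.62) and the complement component C6 (-4.59 ± 0.24) were lower. Of 20 male-biased transcripts 17 were lower and 0 higher (18 and 0 over the list; median -2.48, 3.62e-25, estimated-correlation p = 0.0224). Mt1 and Mt2 were higher by 4.34 ± 0.33 and 4.97 ± 0.29, Hamp2 by 4.35 ± 0.60 and the lipoprotein receptor Vldlr by 4.19 ± 0.37, and asparagine synthetase Asns was lower by -4.79 ± 0.66. Of 29 fetal markers 8 were higher and 1 lower (9 and 1 over the list; median 0.59, 9.61e-05, estimated-correlation p = 0.471).

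The p53 targets were lower to a small degree on full NTBC. Mdm2 differed by -0.62 ± 0.12 (adjusted p = 0.00111), Bax by -0.65 ± 0.13 (0.00154), the nuclease gene Aen by -0.69 ± 0.14 (0.00154) and Gdf15 by -1.60 ± 0.31 (0.00095, arrays of the groups overlapping). Of 34 p53 targets 7 were lower and 1 higher, also over the list (median -0.09, list adjusted p = 0.032, estimated-correlation p = 0.595), and the call was lost with normexp, the deposited values, the stricter filter and the mean of a gene's probes, and without replicate 2 of Fah-/- (0.0642) or of Fah-/- p53-/- mice (0.0548). In all 2830 genes were called, 1288 higher and 1542 lower (45.5% higher). With normexp 22.1% of the calls were higher and the median of all genes was 0.23, against 0.01. Genotype and slide cannot be told apart in this comparison.

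**Figure D4:**
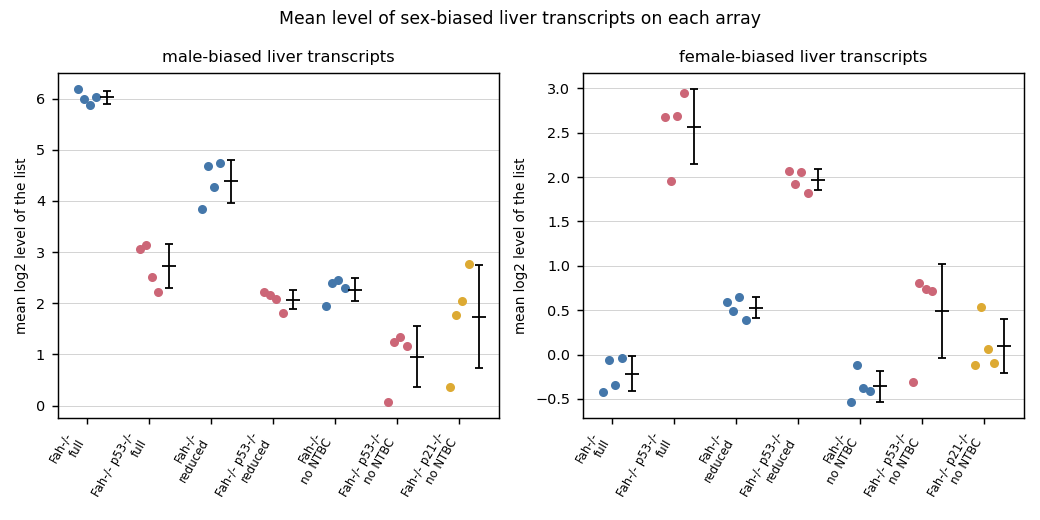
Mean log2 level of the members of the male-biased and female-biased lists on each array, relative to the array's 75th percentile, with 1 point per array in 7 groups and the mean ± SD of 4 arrays beside them in black. On full NTBC all 4 Fah-/- p53-/- arrays lie below all 4 Fah-/- arrays for male-biased and above them for female-biased transcripts, with the same list directions under all scalings tried.

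On reduced NTBC the loss of p53 went with higher cell cycle genes and some higher fetal genes, lower p53 targets and differences in sex-biased genes. Igf2 was higher by 8.85 ± 0.80 (adjusted p = 1.52e-07) and H19 by 8.20 ± 0.68 (3.99e-08). Of 29 fetal markers 9 were higher and 1 lower (12 and 1 over the list; median 0.75, list adjusted p = 0.000604, estimated-correlation p = 0.532; median 0.22 with normexp and 0.23 with the deposited values). The proliferation marker Mki67 was higher by 2.80 ± 0.67 (0.00597), the centromere protein Cenpf at least 9.25-fold (2.75 and 2.60; 0.000727) and the mitotic cyclin Ccnb1 at least 4.25-fold (2.14 and 2.03; 0.0024). Of 34 G2/M and mitosis genes 27 were higher and 0 lower (31 and 0 over the list; median 2.37, list adjusted p = 1.24e-16, estimated-correlation p = 0.471). Their median was 0.79 with normexp and 0.74 with the deposited values. With normexp the calls of Cenpf and Ccnb1 were lost, and with the deposited values that of Ccnb1. Of 34 S phase and replication genes 17 were higher and 1 lower (25 and 1 over the list; 0.74, 1.05e-07, estimated-correlation p = 0.621). Among 34 p53 targets 12 were lower and 0 higher (17 and 2 over the list; -0.29, 2.92e-07, estimated-correlation p = 0.142). Phlda3 differed by -2.24 ± 0.27 (8.25e-06), Aen at -1.58 ± 0.14 (1.26e-07), Ccng1 at -1.53 ± 0.20 (2.49e-05), Bax at -0.83 ± 0.13 (0.000209) and Mdm2 at -0.59 ± 0.12 (0.00181, a call lost with normexp).

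Sex-biased genes differed in the same direction as on full NTBC, with fewer of them called. Sult2a6 was higher by 10.22 ± 0.70, Sult2a4 at least 279-fold (68.7 and 62.0) and Hao2 at least 45.3-fold (9.42 and 8.88; adjusted p = 7.58e-06, the largest of these), and Cyp4a12a was lower by -5.63 ± 0.62, the urinary proteins Mup5 and Mup3 by -5.49 ± 1.26 and -4.55 ± 0.92, and Elovl3 by -4.39 ± 0.89 (0.00437, for Mup5, the largest of these). Of 20 male-biased transcripts 14 were lower and 0 higher (17 and 0 over the list; median -1.75, list adjusted p = 1.64e-15, estimated-correlation p = 0.142). Of 24 female-biased transcripts 9 were higher and 0 lower (16 and 1 over the list; 1.26, 5.41e-06, estimated-correlation p = 0.287). Of 24 endothelial markers 4 were lower and 0 higher (6 and 0 over the list; -0.32, 3.21e-05, estimated-correlation p = 0.515), and Asns was again lower, by -3.15 ± 0.66. The Fah transcript was lower by -0.94 ± 0.21 (0.00374, a call lost with normexp). In all 3176 genes were called, 1999 higher and 1177 lower (62.9% higher). With normexp 220 were, 51.4% higher. Probes well above background were 66.2% to 68.5% on Fah-/- p53-/- and 57.2% to 59.7% on Fah-/- arrays.

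With no NTBC the loss of p53 went with lower p53 targets and with higher cell cycle and fatty acid oxidation genes. Mdm2 was lower by -1.24 ± 0.12 (adjusted p = 7.58e-07; -1.32 with slide as a fixed block and -1.46 within the slide that holds both groups), Ccng1 by -1.54 ± 0.20 (2.73e-05; -1.43 and -1.26), Phlda3 by -2.08 ± 0.27 (2.59e-05; -2.08 and -1.88), Bax by -0.85 ± 0.13 (0.000197; -0.85 and -0.86) and Bbc3 by -0.92 ± 0.17 (0.000961; -1.07 and -1.16). Of 34 p53 targets 15 were lower and 1 higher (16 and 2 over the list; median -0.55, list adjusted p = 8.72e-10, estimated-correlation p = 0.0532), with a median of -0.58 with slide as a block and -0.54 within the slide. The water channel Aqp3 was higher by 4.02 ± 0.34 (6.99e-08; 4.46 and 4.05), the acyl-CoA thioesterase Acot2 by 2.28 ± 0.24 (1.75e-06; 2.09 and 2.27) and the lipid droplet protein Plin4 by 2.62 ± 0.30 (8.65e-06; 2.94 and 2.42). Of 31 genes of fatty acid oxidation and PPARA, the receptor that controls it, 19 were higher and 0 lower (22 and 0 over the list; median 0.57, 4.58e-13, estimated-correlation p = 0.345; 0.57 with slide as a block and 0.61 within the slide). The progenitor marker Cd24a was higher by 2.72 ± 0.40 (0.000102; 3.30 and 2.58) and Nlrp12 at least 14.5-fold (3.67e-05; 3.90-fold with normexp and 2.40-fold with the deposited values).

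Of 34 G2/M and mitosis genes 17 were higher and 0 lower with p53 lost and no NTBC (25 and 0 over the list; median 1.65, list adjusted p = 4.71e-10, estimated-correlation p = 0.621; 1.91 with slide as a block, 1.64 within the slide, and 2.29-fold with normexp and 2.24-fold with the deposited values). Of 34 S phase genes 13 were higher and 0 lower (15 and 0 over the list; 0.73, 2.59e-07, estimated-correlation p = 0.64; 0.78 and 0.82). The S phase factor E2f8 differed by 2.27 ± 0.45 (0.00168; 2.56 and 2.50). Of 32 DNA repair and checkpoint genes 11 were higher and 0 lower (16 and 1 over the list; 0.32, 8.38e-06, estimated-correlation p = 0.453; 0.40 and 0.42). Of 35 plasma proteins 15 were lower and 0 higher (18 and 0 over the list; -0.41, 1.96e-09, estimated-correlation p = 0.331; -0.41 and -0.37), and Cyp7a1 was lower by -2.47 ± 0.54 (0.00407; -2.44 and -1.98). Of 24 endothelial markers 9 were lower and 0 higher (14 and 0 over the list; -0.44, 2.69e-06, estimated-correlation p = 0.453, and adjusted p = 0.743 with a term for sex; -0.24 and -0.39), and with the term for sex their median was 0.08. Of 12 B and plasma cell markers 7 were lower and 0 higher, also over the list (-0.78, 7.44e-05, estimated-correlation p = 0.199, and adjusted p = 0.251 with normexp; -1.08 and -0.73), and with normexp the median was 0.03. Sex itself differed: 4 of 5 sex-linked transcripts were lower and 1, Xist, higher (-5.56, 0.000744, estimated-correlation p = 0.199; -4.05 and -5.47). Over the 12 arrays with slide as a fixed block the calls of E2f8 and Cyp7a1 were lost, and with a term for sex those of Bax (-0.85 ± 0.23), Bbc3 (-1.14 ± 0.30), E2f8 (2.90 ± 0.78) and Cyp7a1 (-2.86 ± 0.96), where the SE grew, and of the sex-linked list (-0.24). Within the slide that of Cyp7a1 was lost.

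In all 2893 genes were called for p53 loss with no NTBC, 1554 higher and 1339 lower. With slide as a fixed block 343 were called over the 12 arrays and 1438 with the spread of all 28, 535 within the slide, 277 with a term for sex, 728 with normexp and 1335 with a fit to the groups compared alone. Without Fah-/- replicate 3 or 4 with no NTBC 1911 and 1915 were called.

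With no NTBC the Fah-/- p21-/- arrays had higher cell cycle genes than Fah-/- arrays, while no p53 target was called. The mitotic regulator Cdc20 was higher by 2.83 ± 0.61 (adjusted p = 0.00653; 3.53 with slide as a fixed block and 3.66 within the slide that holds both groups) and Ccnb1 by 3.60 ± 0.88 (0.0146; 4.69 and 5.02, and 0.0506 without Fah-/- replicate 3, 0.0548 with a fit to the groups compared alone, and at most 0.105 over its alternatives). Of 34 G2/M and mitosis genes 23 were higher and 0 lower (31 and 0 over the list; median 1.96, list adjusted p = 1.29e-16, estimated-correlation p = 0.471; 2.47 with slide as a block, 2.73 within the slide, 2.34 among male arrays, but 1.39 with normexp and 1.195 with the deposited values). Of 34 S phase genes 10 were higher and 0 lower (21 and 0 over the list; 0.71, 1.54e-09, estimated-correlation p = 0.58; 0.80 and 0.74), and of 32 DNA repair genes 11 and 0 (13 and 0 over the list; 0.42, 6.42e-07, estimated-correlation p = 0.345; 0.50 and 0.32). The primase subunit Prim2 was higher by 4.88 ± 0.18 or 29.4-fold (6.47e-15; 4.89 and 4.89, but 7.06-fold with normexp and 4.85-fold with the deposited values), Nlrp12 at least 26.9-fold (1.18e-05; 4.90-fold with normexp and 3.23-fold with the deposited values) and Hmox1 by 1.44 ± 0.28 (0.00315; 1.57 and 1.46). Among the 34 p53 targets 0 were higher and 0 lower in the limma fit, also over the list, against 4 and 3 at an unadjusted p under 0.05 (median 0.09, list adjusted p = 0.593, and 0.473 with fry). Mdm2 differed by -0.05 ± 0.12 (0.858) and Ccng1 at -0.11 ± 0.20 (0.796).

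Interferon and B cell genes were lower in the Fah-/- p21-/- group. Of 29 interferon response genes 10 were lower and 0 higher (16 and 0 over the list; median -0.74, list adjusted p = 4.19e-10, estimated-correlation p = 0.532; -0.58 with slide as a block and -0.64 within the slide). Ifit3 differed by -2.15 ± 0.48 (0.00806; -1.67 and -2.15). Of 12 B and plasma cell markers 6 were lower and 0 higher, also over the list (-0.79, 5.71e-05, estimated-correlation p = 0.199; -0.80 and -1.26, and -0.195 with normexp and -0.25 with the deposited values). The galactosyltransferase B3galt1 was lower by -2.91 ± 0.27 (6.97e-07; -2.82 and -2.78), the pentraxin Apcs by -1.78 ± 0.26 (0.000221; -1.82 and -2.01), Cyp7a1 by -3.14 ± 0.54 (0.00113; -3.08 and -3.54) and the complement component C8a by -2.99 ± 0.44 (0.000216; -2.60 and -3.14). Over the 12 arrays with slide as a fixed block the calls of Cdc20, Ccnb1, Ifit3, Cyp7a1 and C8a were lost, and within the slide those of Hmox1 and Ifit3. The call of Ifit3 was lost also with the spread of all 28 arrays. In all 1529 genes were called, 800 higher and 729 lower. With slide as a fixed block 85 were called over the 12 arrays and 696 with the spread of all 28, 205 within the slide, 545 among male arrays, 183 with normexp and 352 with a fit to the groups compared alone. Without Fah-/- replicate 2 or 4 with no NTBC 847 and 784 were called.

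Set against each other with no NTBC, Fah-/- p53-/- and Fah-/- p21-/- livers differed in p53 and NRF2 targets, while neither the G2/M nor the S phase list passed (0 members called by limma, against 2 and 1 at an unadjusted p under 0.05; medians -0.27 and -0.07, list adjusted p = 0.16 and 0.874, and 0.661 and 0.925 with fry). Of 34 p53 targets 18 were lower and 3 higher in Fah-/- p53-/- mice (21 and 3 over the list; median -0.75, estimated-correlation p = 0.0224; -0.71 with slide as a block, -0.68 within the slide that holds both groups and -0.80 among female arrays). Mdm2 was lower by -1.19 ± 0.12 (adjusted p = 1.39e-06; -1.29 and -1.16), Ccng1 by -1.44 ± 0.20 (7.46e-05; -1.48 and -1.66), Phlda3 by -2.10 ± 0.27 (2.67e-05; -2.19 and -2.39), the kinase Plk2 by -1.54 ± 0.25 (0.000367; -1.78 and -1.98) and Bax by -0.86 ± 0.13 (0.000227; -0.88 and -0.87). Of 38 NRF2 targets 22 were lower and 0 higher (29 and 0 over the list; -0.63, 1.32e-17, estimated-correlation p = 0.199; -0.59 and -0.71), among them Nqo1 (-1.23 ± 0.20, 0.000362; -1.25 and -1.40), Hmox1 (-1.40 ± 0.28, 0.00231; -1.40 and -1.52) and the glutathione transferase Gstm4 (-1.21 ± 0.22, 0.000774; -1.12 and -1.16). Of 31 fatty acid oxidation and PPARA genes 10 were higher and 0 lower (15 and 0 over the list; 0.48, 1.08e-06, estimated-correlation p = 0.58; 0.41 and 0.35), and Aqp3 (3.27 ± 0.34, 1.39e-06; 3.32 and 3.74), Acot2 (1.75 ± 0.24, 5.2e-05; 1.41 and 1.23) and Plin4 (2.46 ± 0.30, 1.64e-05; 2.52 and 3.04) were higher. Of 29 interferon response genes 3 were higher and 0 lower (median 0.67, 0.000164, estimated-correlation p = 0.715; 0.62 and 0.53, the latter not called; 0.131 with fry; median 1.17 without the 2 arrays farthest from their groups). Prim2 was lower by -4.27 ± 0.18 (1.29e-13; -4.37 and -4.37, but -2.126 with normexp and -2.205 with the deposited values) and the Rac1 activator Tiam2 by -5.17 ± 0.83 (0.000317; -5.17 and -5.03). Cdkn1a was not called (0.06 ± 0.43, 0.95). Over the 12 arrays with slide as a fixed block the call of Gstm4 was lost, and within the slide those of Gstm4 and Hmox1. In all 2234 genes were called, 1024 higher and 1210 lower. With slide as a fixed block 188 were called over the 12 arrays and 1057 with the spread of all 28, 530 within the slide, 473 with normexp and 492 with a fit to the groups compared alone. Without Fah-/- p53-/- replicate 1 3666 were called, without replicate 4 1363, and without the arrays farthest from their groups 3707.

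The losses of p53 and of p21 with no NTBC shared 612 genes that differed in the same direction from Fah-/- mice (355 higher and 257 lower, against 61.23 and 48.08 for independent calls), and 12 went in opposite directions. Both comparisons share the Fah-/- arrays, which alone gave a correlation across genes of 0.498 in simulated unchanged groups, against 0.572 observed. With the Fah-/- arrays split between the comparisons the correlation was 0.331 to 0.548 and 94 to 171 genes were shared. With slide as a fixed block 39 genes were shared over the 12 arrays and 268 with the spread of all 28, with a term for sex 73, with normexp 78 and with a fit to the groups compared alone 109. Without Fah-/- replicate 2 or 4 with no NTBC 372 and 304 were shared.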

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

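The tests of the 3 patterns below were chosen after their results were seen, though several use alternatives planned before, and the splits of the arrays were planned before.

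Fah-/- p53-/- livers on full and reduced NTBC had fewer male-biased and more female-biased transcripts than Fah-/- livers. Female animals are argued against, since 8 of 8 Fah-/- p53-/- arrays at these doses had Ddx3y and not Xist above background. Scaling is argued against too, since the smallest median of the lists under the other scalings was 0.683 in size. Because 0 slides hold both genotypes at these doses, genotype and slide cannot be told apart, and genotype, like any difference between the colonies, stays open as untested.

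Cell cycle genes were higher in Fah-/- p53-/- than in Fah-/- livers on reduced NTBC. A single array is argued against, since the lowest G2/M list median with 1 of the 8 arrays left out was 2.13. A loss of hepatocytes alone would raise markers of all other cells alike. Endothelial markers (shift of the mean level -0.31 ± 0.06) and stellate cell and matrix genes (0.36 ± 0.16) moved apart by 3.35 SE, the most of 6 pairs. T and NK cell (0.51 ± 0.25) and macrophage markers (0.58 ± 0.27) shifted with stellate genes, within 1.09 SE of each other. A change in these cells, and so in the hepatocyte share, stays open. The median was as low as 0.74 under other scalings, and fewer Fah-/- probes passed background. Part of the size may come from how dim probes are treated. Genotype cannot be told from slide and stays open as untested.

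With no NTBC, p53 targets were lower in Fah-/- p53-/- mice and cell cycle genes higher in both double mutants. Sex is argued against for the p53 targets and for the G2/M genes of Fah-/- p21-/- mice: among female arrays the median of the p53 targets in Fah-/- p53-/- against Fah-/- p21-/- mice was -0.80, and among male arrays that of the G2/M genes in Fah-/- p21-/- against Fah-/- mice was 2.34. With terms for sex and slide, which assume that their effects add up, the mean level of the G2/M genes was higher in Fah-/- p53-/- than in Fah-/- mice by 2.18 ± 1.02 (1.51 ± 0.53 without them), just over 2 SE against sex as the whole cause. For the S phase genes it was 0.69 ± 0.53, so sex stays open there. Slide is argued against for the p53 targets, with a median of -0.54 within the slide that holds Fah-/- p53-/- and Fah-/- arrays. For the number of genes called between these groups sex stays open: terms for sex and slide left 109, but also raised the median SE 2 times. The genotypes stay open as an untested biological explanation.

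Of 91 checks for an array far from the other 3 of its group, 11 passed, where chance gives about 1 in 20, or 4.55. Fah-/- p53-/- replicate 1 with no NTBC stood apart in male-biased transcripts (0.069, others 1.16 to 1.34), female-biased transcripts (-0.31, others 0.72 to 0.81) and fetal markers (1.61, others 2.34 to 2.41), and replicate 3 of that group in probes well above background (61.7%, others 64.8% to 65.3%). The Fah level stood apart on Fah-/- replicate 1 with no NTBC (-2.71, others -1.97 to -1.82), on Fah-/- replicate 4 on reduced NTBC (0.021, others -0.10 to -0.09) and on Fah-/- p53-/- replicate 1 on reduced NTBC (-1.47, others -0.89 to -0.81). Fah-/- replicate 3 with no NTBC stood apart at the dimmer Trp53 probe (-0.30, others -0.68 to -0.62) and in fetal markers (1.43, others 1.91 to 1.98). Fah-/- p21-/- replicate 3 did so in Cdkn1a (3.57, others 3.09 to 3.15) and Fah-/- replicate 3 on full NTBC in plasma proteins (7.33, others 7.46 to 7.47).

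The responses of the genotypes differed by a test of the difference itself for 2108 genes on reduced NTBC and for 1850 with no NTBC. On reduced NTBC the lists that passed with the preset correlation were the p53 targets (median -0.063), S phase (0.72), G2/M (1.27), lipogenesis (-0.68), cholesterol synthesis (-0.69), endothelial markers (-0.43), male-biased (0.81) and female-biased transcripts (-1.20) and immediate early genes (0.73), each as Fah-/- p53-/- minus Fah-/- mice. With no NTBC they were the p53 targets (-0.45), S phase (0.61), DNA repair (0.36), urea cycle (-0.58), cytochrome P450 (-0.44), fatty acid oxidation (0.48), cholesterol synthesis (-0.77), plasma proteins (-0.16), acute phase (-0.31), T and NK cells (-0.88), B and plasma cells (-0.68), endothelial markers (-0.47), interferon response (-0.34), sex-linked (-5.65), male-biased (1.72) and female-biased transcripts (-1.61) and ribosomal proteins (0.23). None of these 26 passed with an estimated correlation. With normexp the calls of the p53 targets, lipogenesis, cholesterol synthesis, endothelial and female-biased lists on reduced NTBC and of cytochrome P450, plasma proteins and acute phase with none were lost. A term for sex ended those of cytochrome P450 (-0.25), fatty acid oxidation (0.20), acute phase (-0.14), endothelial markers (-0.095) and sex-linked transcripts (-0.77), whose medians shrank, and of plasma proteins (-0.24) and interferon response (-0.37), whose medians did not, and the deposited values that of B and plasma cells. No interferon gene was called by limma, against 8 lower at an unadjusted p under 0.05.

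Leaving out an array ended some of these list calls. On reduced NTBC the call of the p53 targets was lost without Fah-/- replicate 1 on reduced NTBC (median -0.05). That of the immediate early genes was lost without Fah-/- replicates 1 (median 0.56) or 2 (0.66) or Fah-/- p53-/- replicate 4 (0.66) on full NTBC, and without Fah-/- replicates 2 (0.66), 3 (0.64) or 4 (0.78) or Fah-/- p53-/- replicate 2 (0.51) on reduced NTBC. With no NTBC the loss of Fah-/- p53-/- replicate 1 ended the calls of cytochrome P450 (-0.27), plasma proteins (-0.11), acute phase (-0.25), T and NK cells (-0.41) and interferon response (median 0). The call of the plasma proteins was lost also without Fah-/- replicate 3 on full NTBC (-0.10), Fah-/- replicates 2 (-0.11) or 3 (-0.07) with no NTBC, or Fah-/- p53-/- replicates 1 (-0.11) or 2 (-0.15) on full NTBC. For the acute phase this held for Fah-/- p53-/- replicate 1 on full NTBC (-0.31). For the interferon response it held for Fah-/- replicate 1 (-0.26) and Fah-/- p53-/- replicate 4 (-0.13) on full NTBC and for Fah-/- replicates 2 (-0.27) and 4 (-0.27) with no NTBC.

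Other splits of the arrays mix the groups, and called fewer genes in every comparison. The real split had the most of 35, or of 100 for differences between responses, too few to exclude chance. On reduced NTBC the real count was 8072 in Fah-/- mice (highest other 5), 8088 in Fah-/- p53-/- mice (553) and 2108 for their difference (549). For no against full NTBC it was 14390 (17), 14159 (3828) and 1850 (770), and for no against reduced NTBC 13051 (1970) and 12444 (2891). For p53 loss it was 2830 on full NTBC (11), 3176 on reduced NTBC (60) and 2893 with none (1573), for p21 loss 1529 (422) and for p53 against p21 loss 2234 (1489). At full and reduced dose the real split is also the split by slide.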

How the results depend on the processing

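The term for sex, the arrays of a single sex, the leaving out of the 2 far arrays and the fixed slide block with the spread of 28 arrays were chosen after the data were seen. Of 4819 alternative values of 242 called genes named here 4767 kept direction and call, 52 lost the call and 0 reversed, but these genes were mostly chosen because their calls held. Of 2328 for the 103 lists called 2146 kept both, 174 lost the call and 8 reversed. Sizes depended on the scaling: 40 list medians and 57 genes were smaller by over 1.5 times with normexp, 39 and 45 with the deposited values and 8 and 0 with quantile normalization, and 3, 3 and 2 list medians were larger. With an estimated correlation 3 of 203 list tests passed. Unless stated, the cause was not tested.

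The reversed values were, with normexp, -0.032 for G2/M genes and -0.094 for fetal markers on reduced NTBC in Fah-/- p53-/- mice, 0.12 for plasma proteins and 0.043 for the acute phase in the difference between responses to no NTBC, and 0.026 for B cell markers for p53 loss with no NTBC. With a term for sex, endothelial markers for p53 loss with no NTBC were at 0.077. The interferon response in the difference between responses to no NTBC came to 0 without the 2 far arrays, and ran from -0.529 to 0 with each array left out in turn, at 0 without Fah-/- p53-/- replicate 1.

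Counts of calls with normexp were 1996 (reduced NTBC, Fah-/-), 78 and 241 (differences between responses, reduced and none), 6755 and 5698 (none against reduced), 220 and 728 (p53 loss, reduced and none), 183 (p21 loss), 473 (p53 against p21 loss), and 1529, 1080 and 78 for the overlaps of doses in Fah-/-, of genotypes on reduced NTBC and of p53 with p21 loss. The value table gave 2116 and the strict filter 2062 for p53 loss on reduced NTBC. Without a filter, which tests more probes, there were 12235 (reduced, Fah-/- p53-/-), 22528 and 21608 (none against full), 20630 (none against reduced, Fah-/-), 6517 (p53 loss, reduced) and 18158 for the overlap of genotypes with no NTBC. A fit to the groups compared alone, with fewer arrays, gave 1335, 352, 492 and 109 for p53 loss, p21 loss, both against each other and their overlap with no NTBC.

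A minimum change of 2-fold left 2504, 2327 and 1041 for reduced against full NTBC in Fah-/- and Fah-/- p53-/- mice and their difference, 7788, 7700 and 1017 for none against full, 5913 and 5651 for none against reduced, 869, 1094 and 937 for p53 loss at full, reduced and no NTBC, 597 for p21 loss and 662 for p53 against p21 loss. It left 1758, 1010, 5952 and 247 for the overlaps.

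With slide as a fixed block p53 loss, p21 loss, both against each other and their overlap with no NTBC gave 343, 85, 188 and 39 over 12 arrays and 1438, 696, 1057 and 268 with the spread of all 28. Within the slide, with fewer arrays, the first 3 gave 535, 205 and 530. With a term for sex there were 605 for the difference between responses to no NTBC, 277 and 545 for p53 and p21 loss and 73 for their overlap, among male arrays 545 for p21 loss, and without the 2 far arrays 3707 for p53 against p21 loss.

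With each array left out in turn the counts ran from 6580 to 7846 and 6830 to 7711 for reduced against full NTBC in Fah-/- and Fah-/- p53-/- mice, 1398 to 2307 for their difference, 13664 to 14016 and 13605 to 14179 for none against full, 1416 to 2283 for their difference, 12053 to 12659 and 11487 to 12772 for none against reduced, 2066 to 2699, 2214 to 3012 and 1911 to 3394 for p53 loss at full, reduced and no NTBC, 784 to 1491 for p21 loss and 1363 to 3666 for p53 against p21 loss. The overlaps ran from 4829 to 5796, 3728 to 4200, 11247 to 11846 and 304 to 762.

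The replicate number as a block moved no count by over 1.5 times: 8250, 8262 and 2226 for reduced against full and the difference, 14473, 14263 and 2033 for none against full, 13120 and 12544 for none against reduced, 2969, 3352 and 3182 for p53 loss, 1698 for p21 loss, 2339 for p53 against p21 loss, 5941, 4409, 11765 and 721 for the overlaps and 204 list tests. Same-numbered arrays did not deviate together (correlation -0.226 to 0.356, above 0.1 for every number in 0 of 11 comparisons), and 11 of 28 arrays correlated best with their own number, so the numbers are not taken as pairs. Probes at background limit what can be said of dim genes.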

Other observations

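The values of genes in this part were looked at before they were chosen, and the test on the neighbours of Trp53 was written before its result was seen.

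Several single genes differed strongly in comparisons described above. Imp4, a factor of ribosomal RNA processing, was at least 5.02-fold higher in Fah-/- p21-/- than in Fah-/- mice with no NTBC (adjusted p = 2.97e-12, limma, 4 of 4 arrays above 4) and at least 4.23-fold lower in Fah-/- p53-/- than in Fah-/- p21-/- mice (1.58e-11). Both passed with slide as a fixed block and within the slide. The folds were 1.56 and 1.57 with the deposited values, and 2.09 and 1.30 with normexp, where neither passed. The cyclooxygenase Ptgs2 was at least 9.29-fold lower in Fah-/- p53-/- than in Fah-/- p21-/- mice (1.62e-06; 2.09-fold with the deposited values and 1.77-fold with normexp, which did not pass). The mast cell proteases Mcpt4 (at least 14.6-fold, 5.37e-05) and Cpa3 (at least 11.4-fold, 0.000192) were lower in Fah-/- p53-/- than in Fah-/- mice with no NTBC. Both passed within the slide and with the deposited values (2.54- and 2.45-fold), and neither with slide as a block, a term for sex or normexp (2.20- and 2.10-fold).

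On reduced NTBC the electron carrier Cyb561 changed by 3.44 in Fah-/- and by -0.39 in Fah-/- p53-/- mice (difference -3.83 ± 0.32, adjusted p = 8.78e-08, limma), and the recombination cofactor Psmc3ip by 3.79 and 0.09 (-3.71 ± 0.49, 5.45e-05).

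A hypothesis was that some genes that differ between Fah-/- p53-/- and Fah-/- mice at every dose do so because DNA around Trp53 came along from another strain. At all 3 doses 188 genes were called in the same direction, 82 higher and 106 lower. Among the 200 tested neighbours of Trp53, 2 were (1%), against 153 of 14376 other genes (1.06%), a ratio of 0.94 (Fisher's exact p = 1). The 95% interval of the odds ratio reached from 0.112 to 3.50, so a doubling is not excluded and the hypothesis stays open. The demand that the interval exclude a doubling was added after the result was seen, because the bound first written took no account of it.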
